A study of Homo sapiens with 9 samples.

How the data were processed

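RNA was measured on 9 Affymetrix whole-transcript arrays, 3 from untreated MDA-MB-231 cells, 3 after YM-155 for 8 h and 3 after YM-155 for 20 h. Per the labels, the authors made the deposited values with RMA in Affymetrix Expression Console, and the values tested as log2 RMA summaries, 1 for each of 53617 probe sets on each array. The software versions and the genome build were not stated in the labels, so no positions are given.

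Of the 53617 probe sets, 25713 were in the table that links probe sets to genes, 23558 of them with 1 symbol and 2155 with several. The 27904 probe sets outside that table and those with several symbols were left out of the gene tests. Where a gene had several probe sets (618 symbols), the brightest by its mean over the 9 arrays was kept, which gave 22109 genes. Current symbols were taken through the gene identifiers, which changed 3 symbols, and 1215 genes had no match in the reference annotation. No other normalization or filter was applied before the tests. The median level of all genes was 3.89 (log2). Arrays give no count depth, and their number limits the precision stated here.

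The 3 group means were fitted to all 9 arrays in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, with 6 residual and 4.01 prior degrees of freedom. The comparisons were 8 h against control, 20 h against control and 20 h against 8 h. All tests were two-sided, p-values were adjusted over all genes by Benjamini and Hochberg, and genes with an adjusted p under 0.05 were called higher or lower. A count of genes changed at least 2-fold also required an absolute log2 change of 1. An exact permutation test of 3 arrays against 3 cannot give a p under 0.1, so none was used to call genes.

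The comparisons, tests, alternatives, naming rule and 35 gene lists were fixed before the data were examined. The lists covered apoptosis regulators, p53 targets, DNA repair, stress responses, the cell cycle, histones, small RNA classes, ribosomes, mitochondria, metabolism, signalling targets, chromatin, reference genes and markers of other cells. Each list was tested with camera in limma at a preset correlation of 0.01, adjusted over the 35 lists, and again with a correlation estimated for each list. A further 7 lists, named among the other observations, were chosen after seeing the data and only counted. Similarity of the 8 h and 20 h changes was set against 100 simulations (20 for the counts of shared calls) without an effect that shared the same controls. Shared calls were also set against the overlap of independent lists of the same sizes.

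Named genes were the 8 largest rises and 8 largest falls of each comparison with control and the 5 and 5 of 20 h against 8 h, together with BIRC5, MCL1, SLC35F2 and up to 4 called members per list. The largest changes had to pass the adjusted p, have all 3 arrays of a group beyond all 3 of the other (chance gives 10% of genes such a split) and have a mean above the median of all genes. Symbols of unnamed loci, small RNAs, antisense transcripts and those ending in P and a digit were left out of the largest changes. That last clause was meant for pseudogenes but also left out TNFAIP3, which is named through its list. Lists of at most 8 measured members could be named in full.

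Alternatives were a filter on genes below the median level, all probe sets without collapsing, the mean of a gene's probe sets, quantile normalization again, centring on array medians, only the 2 groups compared, array weights, a trended and robust variance, fry, and leaving out each array. The replicate numbers were also used as a block, although deviations of arrays with the same number correlated between -0.318 and 0.111. Counting 8 h replicates 1 and 2 as 1 sample was chosen after seeing the data. In a test on simulated data with the same design, a log2 change of 1 was recovered for 97.0% to 98.5% of genes, and one of 0.5 for 53.7% to 56.7%. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.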

Results

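Gene expression was measured in MDA-MB-231 cells, an established human breast cancer line derived from a pleural effusion, after exposure to YM-155 (sepantronium bromide). YM-155 is a small molecule described as a suppressor of survivin, the inhibitor of apoptosis protein encoded by BIRC5. Total RNA from 9 samples was hybridised to Affymetrix whole-transcript arrays, 3 in each of 3 groups. The control group received no treatment. The 8 h group received YM-155 in increments that added up to 83 ng/ml. The 20 h group received 14.6 ng/ml, the concentration given as its LC50. Dose and time thus differed together, so no comparison isolates either one, and no time or vehicle was given for the controls. Each array gave 1 RMA value on the log2 scale for each probe set, with array medians from 3.11 to 3.20, and 22109 genes were tested. The number of arrays limits the precision of every value. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

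The arrays fell into the 3 groups along the first 2 principal components, which held 60.6% and 15.8% of the variance. Control replicate 3 lay apart from the other controls. Over the 11054 genes above the median level, its differences from controls 1 and 2 had SDs of 0.312 and 0.313 log2 units, against 0.187 between those 2. Immediate early genes had a median 0.49 log2 units higher in control replicate 3 than in the other controls, NF-kB genes 0.28, ATF4 genes 0.26 and G1/S genes 0.17, while G2/M genes had a median difference of -0.27. Shifts of at least 0.10 in size were also seen for YAP/TAZ targets (0.17), luminal markers (0.17), histone genes (0.16), NRF2 targets (0.14), pro-apoptotic (0.14) and pro-survival BCL2 genes (0.11), proteasome subunits (-0.12) and inhibitors of apoptosis (-0.12). The closest pair was 8 h replicates 1 and 2, whose difference had an SD of 0.147.

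The first comparison asked which transcripts differed between cells given up to 83 ng/ml YM-155 for 8 h and untreated cells. Stress and growth factor response genes were among those that rose: TNFAIP3, an inhibitor of NF-kB signalling, rose by 3.53 (SE 0.25, limma adjusted p = 2.31e-05), from 5.92 ± 0.65 to 9.46 ± 0.04 (SD, n = 3). SIK1, a salt-inducible kinase, rose by 2.76, ATF3, a stress-induced transcription factor, by 2.63, and SLC2A3, a glucose transporter, by 2.13. TXNIP, an inhibitor of thioredoxin, fell by 2.04 (SE 0.11, limma adjusted p = 8.91e-06), from 8.71 ± 0.15 to 6.67 ± 0.17 (SD, n = 3). In limma, 1310 genes were higher and 1388 lower, together 12.2% of those tested. At least 2-fold, 232 were higher and 63 lower. More genes were higher than lower over all probe sets (2529 and 1724), with the replicate number as a block (1133 and 1071) and with 8 h replicates 1 and 2 counted as 1 (959 and 844). The same was so without control replicate 1 (1020 and 951), 2 (985 and 974) or 3 (1512 and 1411) and without 8 h replicate 1 (987 and 820), 2 (964 and 876) or 3 (976 and 874). In other settings more genes stayed lower than higher. These included genes above the median level only (1427 higher and 1603 lower) and the mean of a gene's probe sets (1311 and 1373).

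BIRC5 (probe set 16838359) fell at 8 h by 0.47 (SE 0.12, limma adjusted p = 0.0311), from 6.46 ± 0.19 to 5.99 ± 0.13 (SD, n = 3). This call ended in several settings, with adjusted p between 0.0609 and 0.114 without any 1 of the 8 h arrays, 0.107 without control replicate 1 and 0.105 without control replicate 2. MCL1, a pro-survival member of the BCL2 family, rose by 0.75 (SE 0.07, limma adjusted p = 0.000153). The log2 difference of SLC35F2, the carrier reported to bring YM-155 into cells, was -0.08 (SE 0.10, limma adjusted p = 0.713). Of the 7 inhibitor of apoptosis genes measured, 1 fell, BIRC5, and 0 rose, both over all genes and adjusted over the list alone. The list as a whole did not pass (camera adjusted p = 0.503). Of 5 pro-survival BCL2 genes, 1 rose, MCL1, with 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.418). Among 11 pro-apoptotic members of the family, the BH3-only genes PMAIP1 and BCL2L11 rose by 0.90 and 0.59 and 0 fell, as adjusted over the list alone (camera adjusted p = 0.503).

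Cell cycle and repair lists moved downward at 8 h. Of the homologous recombination and Fanconi genes, 0 of 22 rose and 11 fell (0 and 16 adjusted over the list alone), with a median log2 change of -0.46 (camera adjusted p = 9.2e-11). FANCF, a subunit of the Fanconi core complex, fell by 1.05 and RAD54L, a recombination helicase, by 0.88. Of the G1/S and replication genes, 0 of 37 rose and 22 fell (1 and 27 adjusted over the list alone), with a median of -0.40 (camera adjusted p = 3.75e-15, adjusted p = 0.0666 with an estimated correlation). PRIM1, the catalytic primase subunit, fell by 1.11 and POLE2, a subunit of DNA polymerase epsilon, by 1.10. Without control replicate 3, 16 of these genes fell. Of the G2/M and mitosis genes, 1 of 49 rose and 14 fell (1 and 16 adjusted over the list alone), with a median of -0.26 (camera adjusted p = 2.76e-07, adjusted p = 0.139 with an estimated correlation). CCNF, which encodes cyclin F, fell by 1.14, while PTTG1, which encodes securin, rose by 0.73. Without control replicate 3, 18 of this list fell. Of the replication-dependent histone genes, 0 of 30 rose and 8 fell (0 and 8 adjusted over the list alone), with a median of -0.13 (camera adjusted p = 0.00807, adjusted p = 0.139 with an estimated correlation). They were higher in control replicate 3 by a median of 0.16, and without it 6 fell.

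Stress and signalling lists moved upward at 8 h. Of the immediate early genes, 18 of 31 rose and 2 fell (20 and 2 adjusted over the list alone), with a median of 0.70 (camera adjusted p = 4.96e-13, adjusted p = 0.146 with an estimated correlation). FOSB rose by 2.19 and DUSP1, a MAP kinase phosphatase, by 1.97. EGR1 differed by 1.96 (SE 0.56, limma adjusted p = 0.0467), a call that ended without control replicate 1 (adjusted p = 0.147), without control replicate 2 (0.156) and without each treated array (0.0732 to 0.128). Of the NF-kB and cytokine genes, 12 of 26 rose and 0 fell (14 and 0 adjusted over the list alone), with a median of 0.40 (camera adjusted p = 6.92e-08, adjusted p = 0.0813 with an estimated correlation). CXCL8, the neutrophil chemokine, rose by 2.05 and PTGS2, an inducible cyclooxygenase, by 1.74. Of the ATF4 and integrated stress response genes, 11 of 25 rose and 1 fell (13 and 1 adjusted over the list alone), with a median of 0.33 (camera adjusted p = 5.58e-07, adjusted p = 0.0644 with an estimated correlation). SLC7A11, the cystine transporter, rose by 1.31. Control replicate 3 was itself higher for these lists, as given above. Without it, 22 immediate early, 15 NF-kB and 12 ATF4 genes rose.

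Of the hypoxia and glycolysis genes, 14 of 28 rose and 0 fell (18 and 1 adjusted over the list alone), with a median of 0.33 (camera adjusted p = 1.72e-13). ADM, which encodes adrenomedullin, rose by 1.66 and HK2, a hexokinase, by 1.48. Of the cholesterol synthesis genes, 7 of 19 rose and 1 fell (8 and 1 adjusted over the list alone), with a median of 0.23 (camera adjusted p = 5.59e-06). INSIG1, a feedback regulator of sterol synthesis, rose by 1.56 and HMGCS1, which makes HMG-CoA, by 1.51. Of the NRF2 targets, 7 of 24 rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 0.17 (camera adjusted p = 1.23e-06, adjusted p = 0.0706 with an estimated correlation). They were higher in control replicate 3 by a median of 0.14, and without it 7 rose. GCLC, of glutathione synthesis, rose by 1.20 and HMOX1, heme oxygenase 1, by 0.92. Of the cytosolic heat shock genes, 4 of 16 rose and 1 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.00687, adjusted p = 0.0784 with an estimated correlation), with CHORDC1, an HSP90 cochaperone, up by 2.44. Of the endoplasmic reticulum chaperones, 4 of 18 rose and 2 fell (4 and 5 adjusted over the list alone, camera adjusted p = 0.873). Of the p53 targets, 8 of 25 rose and 2 fell (8 and 3 adjusted over the list alone, camera adjusted p = 0.015, adjusted p = 0.115 with an estimated correlation), with GADD45A up by 1.39 and CDKN1A, the p21 cyclin-dependent kinase inhibitor, by 0.96.

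Small nucleolar RNA genes rose at 8 h: 50 of 238 rose and 9 fell (58 and 11 adjusted over the list alone), with a median of 0.11 (camera adjusted p = 5.59e-06). Of the small nuclear RNA genes, 18 of 188 rose and 2 fell (18 and 2 adjusted over the list alone, camera adjusted p = 0.00387), and RNU12, of the minor spliceosome, rose by 1.95. The microRNA genes moved both ways, 42 of 1043 rose and 41 fell (30 and 29 adjusted over the list alone, camera adjusted p = 0.503), and the MIR21 probe set fell by 1.87. Of the numbered zinc finger genes, 20 of 476 rose and 75 fell (25 and 91 adjusted over the list alone), with a median of -0.10 (camera adjusted p = 0.000395), and ZNF79 fell by 1.24. Of the mitochondrial ribosomal proteins, 2 of 70 rose and 11 fell (2 and 13 adjusted over the list alone, camera adjusted p = 1.48e-06, adjusted p = 0.0802 with an estimated correlation), while nuclear-encoded respiratory chain subunits gave 0 of 50 higher and 6 lower (0 and 6 adjusted over the list alone, camera adjusted p = 0.00528, adjusted p = 0.296 with an estimated correlation). Of the cytosolic ribosomal proteins, 9 of 54 rose and 2 fell (12 and 2 adjusted over the list alone, camera adjusted p = 0.015, adjusted p = 0.309 with an estimated correlation), a call that ended without control replicate 1 (adjusted p = 0.0828). Of the extracellular matrix and mesenchymal genes, 6 of 36 rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.00312), with the transcription factor SNAI2 up by 1.62. Of the YAP/TAZ targets, 7 of 24 rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.0117, adjusted p = 0.139 with an estimated correlation), with NUAK2 up by 1.99. Their median change was 0.078, against a shift of 0.17 in control replicate 3, without which 8 rose and 2 fell.

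The remaining lists did not pass camera at 8 h. The mitochondrially encoded list gave 0 of 19 higher and 1 lower (0 and 1 adjusted over the list alone, camera adjusted p = 0.971). Proteasome subunits gave 0 of 35 higher and 4 lower (0 and 4 adjusted over the list alone, camera adjusted p = 0.503). Aminoacyl-tRNA synthetases gave 1 of 16 higher and 1 lower (1 and 1 adjusted over the list alone, camera adjusted p = 0.503). Interferon-stimulated genes gave 3 of 32 higher and 3 lower (4 and 5 adjusted over the list alone, camera adjusted p = 0.851). Among autophagy and lysosome genes, 7 of 35 rose and 3 fell (7 and 5 adjusted over the list alone, camera adjusted p = 0.225), with GABARAPL1, an autophagosome protein gene, up by 1.10. Chromatin modifiers gave 12 of 65 higher and 7 lower (15 and 7 adjusted over the list alone, camera adjusted p = 0.198), with the histone demethylase KDM3A up by 1.28. Of the reference genes, 1 of 10 rose and 2 fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.63). Markers of other cells gave 3 of 20 higher and 0 lower (3 and 0 adjusted over the list alone) for luminal epithelium (camera adjusted p = 0.559), and leukocyte markers gave 0 of 18 higher and 0 lower (0 and 0 adjusted over the list alone, camera adjusted p = 0.195). Olfactory receptor genes, which breast cells are not known to use, gave 4 of 354 higher and 2 lower (1 and 0 adjusted over the list alone, camera adjusted p = 0.335). Camera passed 20 of the 35 lists at 8 h, 13 upward and 7 downward, and 7 of them also with an estimated correlation.

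The second comparison set cells given 14.6 ng/ml for 20 h against untreated cells. Genes of mitosis and DNA repair fell: FANCI, of the Fanconi anaemia repair pathway, fell by 3.26 (SE 0.10, limma adjusted p = 7.51e-08), from 7.91 ± 0.20 to 4.65 ± 0.09 (SD, n = 3). TOP2A, the DNA topoisomerase of dividing cells, fell by 2.79, the centromere gene CENPI by 3.09, the cohesion factor DSCC1 by 3.09 and the centriole kinase PLK4 by 2.68. TNFAIP3 rose by 4.25, and FOSB, ARC and EGR1, all immediate early genes, rose by 4.14, 4.13 and 4.03. In limma, 2894 genes were higher and 3810 lower, 30.3% of those tested. At least 2-fold, 585 were higher and 864 lower.

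BIRC5 fell at 20 h by 1.24 (SE 0.12, limma adjusted p = 2.75e-05), to 5.22 ± 0.15 (SD, n = 3). That change lay within the quartiles of the G2/M and mitosis list at 20 h (-2.06 to -1.13), so it was not particular to BIRC5. At 8 h the change of BIRC5 lay below the quartiles of that list (-0.38 to -0.11). MCL1 rose by 0.54 (SE 0.07, limma adjusted p = 0.000248), and SLC35F2 differed by 0.08 (SE 0.10, limma adjusted p = 0.591). Of the inhibitor of apoptosis genes, 0 of 7 rose and 3 fell (0 and 3 adjusted over the list alone, camera adjusted p = 0.0475, adjusted p = 0.226 with an estimated correlation). Besides BIRC5, BIRC2 fell by 0.70 and NAIP fell by 0.75. The list's call also ended without control replicate 1 (adjusted p = 0.0686), control replicate 2 (0.0636), 20 h replicate 1 (0.0507) or 20 h replicate 3 (0.0688), and with repeated quantile normalization (0.0971). Centred arrays (0.0617), only the 2 groups compared (0.0505) and 8 h replicates 1 and 2 counted as 1 (0.050) ended it too. Of the pro-survival BCL2 genes, 1 of 5 rose and 1 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.628), and BCL2 itself fell by 1.12. Of the pro-apoptotic BCL2 genes, 3 of 11 rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.0437, adjusted p = 0.343 with an estimated correlation), with BCL2L11 up by 1.30, PMAIP1 by 1.26 and BBC3 by 0.89. That call ended without control replicate 1 (adjusted p = 0.0588), control replicate 2 (0.0667) or 20 h replicate 3 (0.053), and with only the 2 groups compared (0.0538).

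Nearly the whole of each cell cycle list fell at 20 h. Of the G2/M and mitosis genes, 1 of 49 rose and 48 fell (1 and 48 adjusted over the list alone), 39 of them at least 2-fold, with a median of -1.55 (camera adjusted p = 1.66e-32). NDC80, of the outer kinetochore, fell by 2.92 and the mitotic kinesin KIF20B by 2.60. Of the G1/S and replication genes, 0 of 37 rose and 34 fell (0 and 35 adjusted over the list alone), with a median of -1.49 (camera adjusted p = 1.06e-24). MCM10, a replication initiation factor, fell by 2.30 and TYMS, thymidylate synthase, by 2.14. Of the homologous recombination and Fanconi genes, 0 of 22 rose and 19 fell (0 and 20 adjusted over the list alone), with a median of -1.67 (camera adjusted p = 2.85e-17), and the helicase genes BRIP1 and BLM fell by 2.74 and 2.36. Control replicate 3 was lower for G2/M genes than the other controls. Without it, 48 G2/M and 33 G1/S genes fell. Histone genes moved both ways, 13 of 30 rose and 6 fell (13 and 6 adjusted over the list alone, camera adjusted p = 0.0453, adjusted p = 0.226 with an estimated correlation), in which H2BC18 rose by 2.50 and H2BC14 fell by 1.30. Without control replicate 3, which was higher for them, 11 rose and 6 fell. Their call ended without control replicate 1 (0.0727), control replicate 2 (0.0525) or 20 h replicate 1 (0.0689) and with repeated quantile normalization (0.0699), only the 2 groups compared (0.0538) or 8 h replicates 1 and 2 counted as 1 (0.050).

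Of the immediate early genes, 26 of 31 rose and 3 fell (27 and 3 adjusted over the list alone), with a median of 1.72 (camera adjusted p = 1.0e-14, adjusted p = 0.137 with an estimated correlation). JUNB rose by 3.14 and ATF3 by 3.57. Of the NF-kB and cytokine genes, 17 of 26 rose and 1 fell (19 and 1 adjusted over the list alone), with a median of 0.72 (camera adjusted p = 4.23e-10, adjusted p = 0.0593 with an estimated correlation), and IL11 rose by 2.57. Of the ATF4 genes, 15 of 25 rose and 1 fell (16 and 1 adjusted over the list alone), with a median of 0.60 (camera adjusted p = 1.32e-07), and PPP1R15A, a phosphatase subunit acting on eIF2, rose by 2.40. Control replicate 3 was higher than the other controls for these 3 lists. Without it, 27 immediate early, 17 NF-kB and 15 ATF4 genes rose. Of the NRF2 targets, 17 of 24 rose and 0 fell (17 and 0 adjusted over the list alone), with a median of 0.39 (camera adjusted p = 1.66e-08), and HMOX1 rose by 1.87. Of the heat shock genes, 11 of 16 rose and 2 fell (12 and 2 adjusted over the list alone), with a median of 0.49 (camera adjusted p = 8.21e-05), and HSPA6, an inducible HSP70, rose by 3.05. Of the endoplasmic reticulum chaperones, 9 of 18 rose and 0 fell (9 and 0 adjusted over the list alone, camera adjusted p = 0.00112, adjusted p = 0.067 with an estimated correlation), and HSPA5, the chaperone BiP, rose by 1.14. Of the cholesterol synthesis genes, 14 of 19 rose and 1 fell (15 and 1 adjusted over the list alone), with a median of 0.91 (camera adjusted p = 4.23e-10). HMGCS1 rose by 2.93, from 5.29 ± 0.13 to 8.22 ± 0.08 (SD, n = 3).

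Small nucleolar RNA genes rose at 20 h: 104 of 238 rose and 4 fell (107 and 4 adjusted over the list alone), with a median of 0.28 (camera adjusted p = 4.76e-12), and SNORA72 rose by 2.14. Of the cytosolic ribosomal proteins, 31 of 54 rose and 1 fell (33 and 1 adjusted over the list alone), with a median of 0.34 (camera adjusted p = 3.89e-08, adjusted p = 0.0545 with an estimated correlation), and RPL28 rose by 1.31. Of the mitochondrial ribosomal proteins, 5 of 70 rose and 32 fell (7 and 34 adjusted over the list alone, camera adjusted p = 0.000459, adjusted p = 0.148 with an estimated correlation), and MRPL39 fell by 1.24. Of the numbered zinc finger genes, 45 of 476 rose and 154 fell (47 and 159 adjusted over the list alone), with a median of -0.15 (camera adjusted p = 0.000481), and ZNF100 fell by 1.73. Of the hypoxia and glycolysis genes, 12 of 28 rose and 2 fell (12 and 5 adjusted over the list alone), with a median of 0.10 (camera adjusted p = 0.0183, adjusted p = 0.148 with an estimated correlation). Without control replicate 2 that median was -0.00067 (adjusted p = 0.0147). Of the proteasome subunits, 0 of 35 rose and 10 fell (0 and 10 adjusted over the list alone, camera adjusted p = 0.0437, adjusted p = 0.351 with an estimated correlation), and PSMD5, an assembly factor, fell by 1.16. That call ended without control replicate 2 (0.114) or 20 h replicate 3 (0.0922) and with repeated quantile normalization (0.104). Of the reference genes, 0 of 10 rose and 4 fell (0 and 4 adjusted over the list alone, camera adjusted p = 0.0183, adjusted p = 0.0854 with an estimated correlation), and IPO8 fell by 1.26.

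Markers of other cell types and olfactory receptor genes also passed at 20 h. Of the luminal markers, 6 of 20 rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.0324, adjusted p = 0.344 with an estimated correlation), with TFF1, a secreted trefoil peptide, up by 1.38 and CLDN3, a tight junction gene, by 1.00. Control replicate 3 was higher for them by a median of 0.17, and without it 7 rose and 0 fell. The luminal call ended without control replicate 1 (0.0588) or 20 h replicate 1 (0.0512). Of the leukocyte markers, 6 of 18 rose and 0 fell (6 and 0 adjusted over the list alone, camera adjusted p = 0.0371, adjusted p = 0.148 with an estimated correlation), with CD68 up by 0.68. The leukocyte call ended without control replicate 1 (0.0546) or 20 h replicate 3 (0.053). CD68 was already at 9.29 to 9.66 in the controls. The called members CD14, CD79A and TYROBP were below the median level of all genes (3.89) in every control array. Of the olfactory receptor genes, 25 of 354 rose and 6 fell (8 and 5 adjusted over the list alone), with a median of 0.11 (camera adjusted p = 0.00665, adjusted p = 0.0702 with an estimated correlation). When only genes above the median level were tested, camera passed 14 lists at 20 h. The adjusted p was then over the threshold for the mitochondrial ribosomal (0.0619), zinc finger (0.0747), reference gene (0.133), proteasome (0.316), olfactory (0.529) lists, and for the histone (0.164), inhibitor of apoptosis (0.126), luminal (0.0618) and pro-apoptotic BCL2 (0.0516) lists. Repeated quantile normalization ended the calls of the leukocyte (0.0699) and olfactory lists (0.128).

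The other lists did not pass camera at 20 h. Of the p53 targets, 10 of 25 rose and 6 fell (10 and 7 adjusted over the list alone, camera adjusted p = 0.172), with SESN2 up by 2.65 and CDKN1A by 1.78. The microRNA genes gave 70 of 1043 higher and 75 lower (45 and 56 adjusted over the list alone, camera adjusted p = 0.628), and the MIRLET7A2 probe set fell by 3.00. Small nuclear RNA genes gave 21 of 188 higher and 12 lower (18 and 9 adjusted over the list alone, camera adjusted p = 0.327), and respiratory chain subunits 3 of 50 higher and 9 lower (3 and 7 adjusted over the list alone, camera adjusted p = 0.0976). The mitochondrially encoded list gave 2 of 19 higher and 2 lower (2 and 2 adjusted over the list alone, camera adjusted p = 0.666). Its 4 called members, MTRNR2L2, MTRNR2L3, TRNT1 and TRNP1, are nuclear genes taken in by the name rule. Aminoacyl-tRNA synthetases gave 3 of 16 higher and 4 lower (3 and 4 adjusted over the list alone, camera adjusted p = 0.628), and FARSB fell by 1.14. Interferon-stimulated genes gave 7 of 32 higher and 12 lower (7 and 12 adjusted over the list alone, camera adjusted p = 0.306), where OAS3 fell by 1.46 and IRF7 rose by 0.98. Of the YAP/TAZ targets, 9 of 24 rose and 7 fell (10 and 7 adjusted over the list alone, camera adjusted p = 0.198), with GADD45B up by 2.75. Of the extracellular matrix and mesenchymal genes, 10 of 36 rose and 4 fell (11 and 5 adjusted over the list alone, camera adjusted p = 0.051), and SNAI1, a repressor of E-cadherin, rose by 3.32. Autophagy genes gave 9 of 35 higher and 7 lower (10 and 7 adjusted over the list alone, camera adjusted p = 0.231), with the sialidase NEU1 up by 1.54. Chromatin modifiers gave 19 of 65 higher and 24 lower (20 and 27 adjusted over the list alone, camera adjusted p = 0.489), with the deacetylase SIRT1 up by 1.72. Camera passed 23 of the 35 lists, 15 upward and 8 downward, and 9 also with an estimated correlation. REXO1L1P, a pseudogene with near-identical copies, rose by 3.18, a value that its copies leave uncertain.

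**Figure D1:**
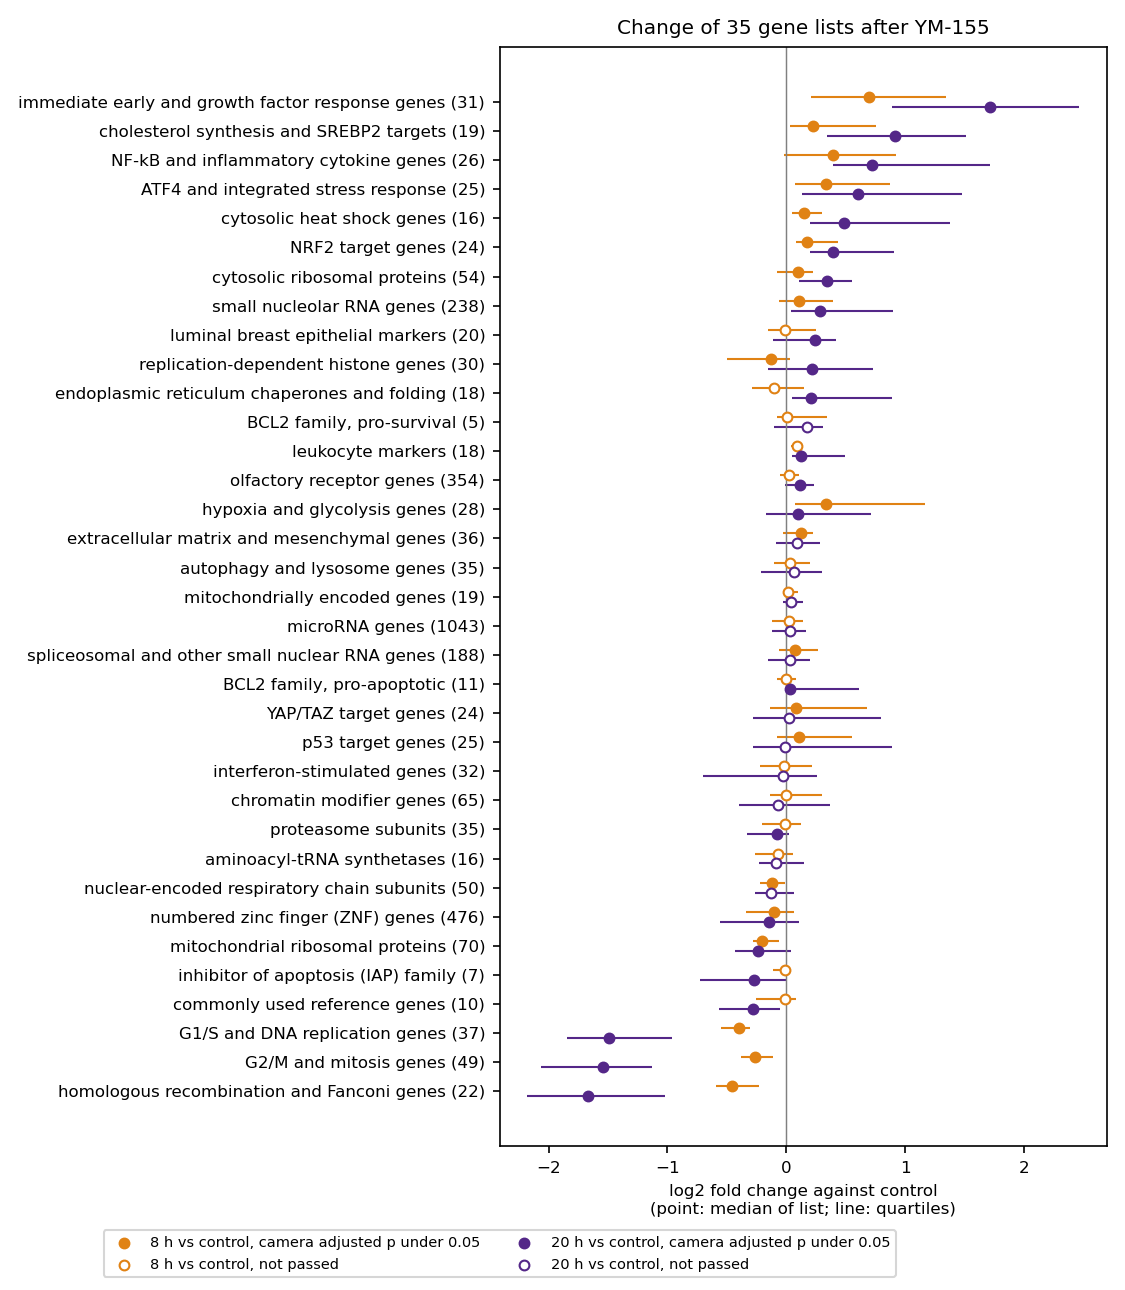
Median log2 fold change against control (horizontal axis) of each of the 35 gene lists, with the number of genes measured in brackets, at 8 h (orange) and 20 h (purple). Lines span the quartiles of a list's members, filled points passed camera and open points did not. The G2/M list lies at -0.26 at 8 h and -1.55 at 20 h, and the immediate early list at 0.70 and 1.72.

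The third comparison set the 20 h group against the 8 h group, which differed in dose as well as time. BIRC5 was lower at 20 h by a log2 difference of -0.77 (SE 0.12, limma adjusted p = 0.00124). MCL1 differed by -0.21 (SE 0.07, limma adjusted p = 0.0706) and SLC35F2 by 0.16 (SE 0.10, limma adjusted p = 0.291). Mitosis genes were lower at 20 h, with differences of -2.72 for PLK4, -2.48 for the kinetochore motor gene CENPE and -2.47 for the condensin subunit NCAPG. ARC, RASD1, HSPA6 and RGS2, a regulator of G protein signalling, were higher by 3.31, 2.79, 2.75 and 2.69. In limma, 1979 genes were higher and 3012 lower at 20 h, 22.6% of those tested. At least 2-fold, 248 were higher and 396 lower. Without 8 h replicate 3, 1314 genes were higher.

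Of the G2/M genes, 0 of 49 rose and 44 fell (0 and 45 adjusted over the list alone) from 8 h to 20 h, with a median of -1.33 (camera adjusted p = 1.86e-36). The G1/S genes gave 0 of 37 higher and 30 lower (0 and 31 adjusted over the list alone), with a median of -0.94 (camera adjusted p = 2.69e-23), and the recombination and Fanconi genes 0 of 22 higher and 17 lower (0 and 18 adjusted over the list alone), with a median of -1.09 (camera adjusted p = 3.62e-15). Among cholesterol synthesis genes, 13 of 19 rose and 0 fell (15 and 0 adjusted over the list alone), with a median of 0.47 (camera adjusted p = 2.64e-10), and DHCR7, of the last step, rose by 1.30. Endoplasmic reticulum chaperones gave 10 of 18 higher and 1 lower (11 and 1 adjusted over the list alone, camera adjusted p = 4.41e-05), heat shock genes 7 of 16 higher and 1 lower (8 and 1 adjusted over the list alone, camera adjusted p = 0.000478) and small nucleolar RNA genes 72 of 238 higher and 19 lower (77 and 21 adjusted over the list alone, camera adjusted p = 3.56e-06). The hypoxia and glycolysis list went the other way, with 2 of 28 higher and 13 lower (2 and 15 adjusted over the list alone) and a median of -0.23 (camera adjusted p = 0.000283, adjusted p = 0.0775 with an estimated correlation). PDK1, a kinase that inhibits pyruvate dehydrogenase, fell by 1.40, while TPI1, triosephosphate isomerase, rose by 1.21. Histone genes gave 13 of 30 higher and 2 lower (16 and 2 adjusted over the list alone, camera adjusted p = 3.89e-05, adjusted p = 0.0579 with an estimated correlation), cytosolic ribosomal proteins 21 of 54 higher and 1 lower (28 and 1 adjusted over the list alone, camera adjusted p = 8.83e-07, adjusted p = 0.0775 with an estimated correlation), and immediate early genes 18 of 31 higher and 1 lower (21 and 1 adjusted over the list alone, camera adjusted p = 2.64e-10, adjusted p = 0.212 with an estimated correlation). NF-kB genes gave 11 of 26 higher and 1 lower (16 and 1 adjusted over the list alone, camera adjusted p = 3.56e-06, adjusted p = 0.128 with an estimated correlation) and ATF4 genes 12 of 25 higher and 3 lower (13 and 3 adjusted over the list alone, camera adjusted p = 0.000297, adjusted p = 0.128 with an estimated correlation). The NRF2 list gave 10 of 24 higher and 1 lower (12 and 1 adjusted over the list alone, camera adjusted p = 0.00179, adjusted p = 0.185 with an estimated correlation). Pro-apoptotic BCL2 genes gave 4 of 11 higher and 0 lower (4 and 0 adjusted over the list alone, camera adjusted p = 0.018, adjusted p = 0.291 with an estimated correlation), and reference genes 0 of 10 higher and 5 lower (0 and 5 adjusted over the list alone, camera adjusted p = 0.0167, adjusted p = 0.101 with an estimated correlation). The reference gene call ended when only genes above the median level were tested (adjusted p = 0.153). The inhibitor of apoptosis list gave 0 of 7 higher and 3 lower (0 and 3 adjusted over the list alone, camera adjusted p = 0.0432, adjusted p = 0.218 with an estimated correlation), a call that ended without control replicate 2 (0.0599), 8 h replicate 3 (0.0595) or 20 h replicate 3 (0.0701). It also ended with genes above the median level only (0.114), repeated quantile normalization (0.0914), centred arrays (0.0574), only the 2 groups compared (0.068) and array weights (0.0521). Luminal markers gave 4 of 20 higher and 0 lower (7 and 0 adjusted over the list alone, camera adjusted p = 0.0182, adjusted p = 0.352 with an estimated correlation), which ended without 8 h replicate 3 (0.0545). Olfactory receptor genes gave 16 of 354 higher and 5 lower (4 and 3 adjusted over the list alone, camera adjusted p = 0.0167, adjusted p = 0.112 with an estimated correlation), which ended without 8 h replicate 2 (0.0607), with repeated quantile normalization (0.181) and among genes above the median level (0.71). Camera passed 19 of the 35 lists, 13 upward and 6 downward, and 7 of them also with an estimated correlation.

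**Figure D2:**
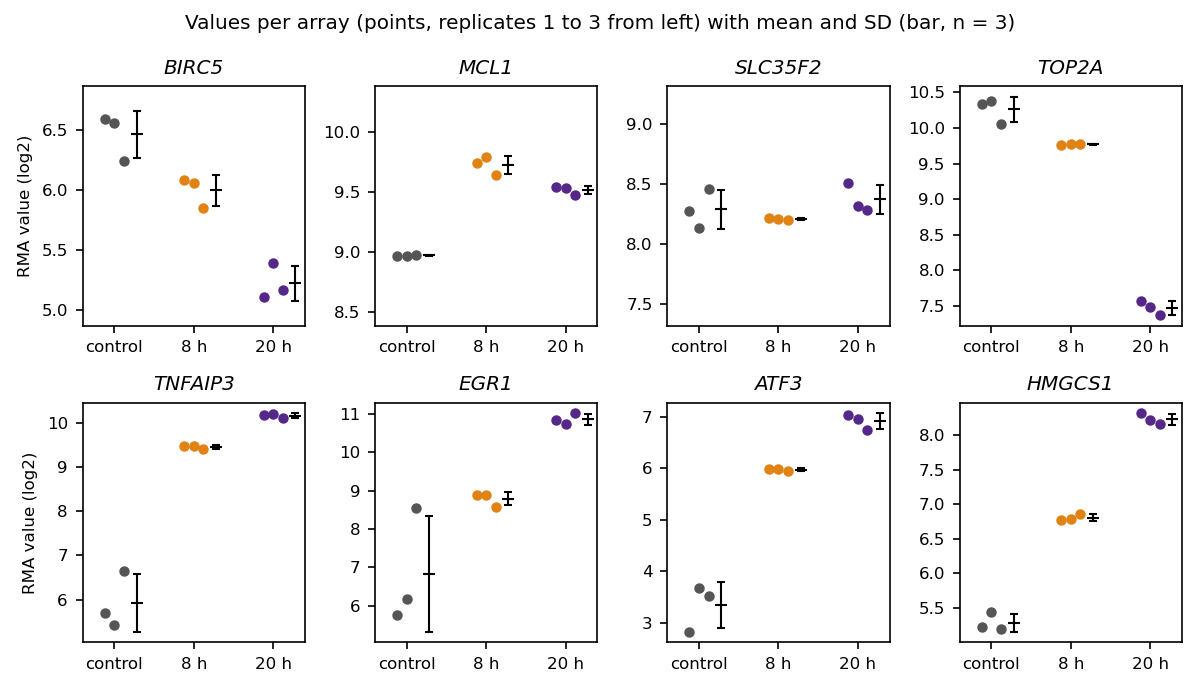
RMA values (vertical axes, log2) of 8 genes in each array of the control, 8 h and 20 h groups. Points are single arrays and bars give the mean and SD of 3. BIRC5 has group means of 6.46, 5.99 and 5.22, and the highest EGR1 control is replicate 3.

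Fold changes at 8 h and 20 h against control were compared across genes, which are not independent replicates. Pearson's r was 0.652, against 0.501 in simulations with no effect and the same shared controls. The covariance was 0.102, against 0.00793 simulated, a difference of 0.0940. Genes higher at both times numbered 927, genes lower at both 1141, and 66 genes had opposite calls. Independent lists of the same sizes would share 171.5, 239.2 and 407.4 genes. The 20 simulations with shared controls and no effect gave means of 0, 0.05 and 0 genes. Almost no gene is called without an effect, so these means were bound to be near 0 and say nothing about the overlap. The simulated covariance already holds the part that comes from spread between the shared controls, at the spread pooled over the 3 groups. The overlap of calls beyond independent lists may still come in part from the shared controls. The 3 controls could not be split with 2 in each part to test this.

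**Figure D3:**
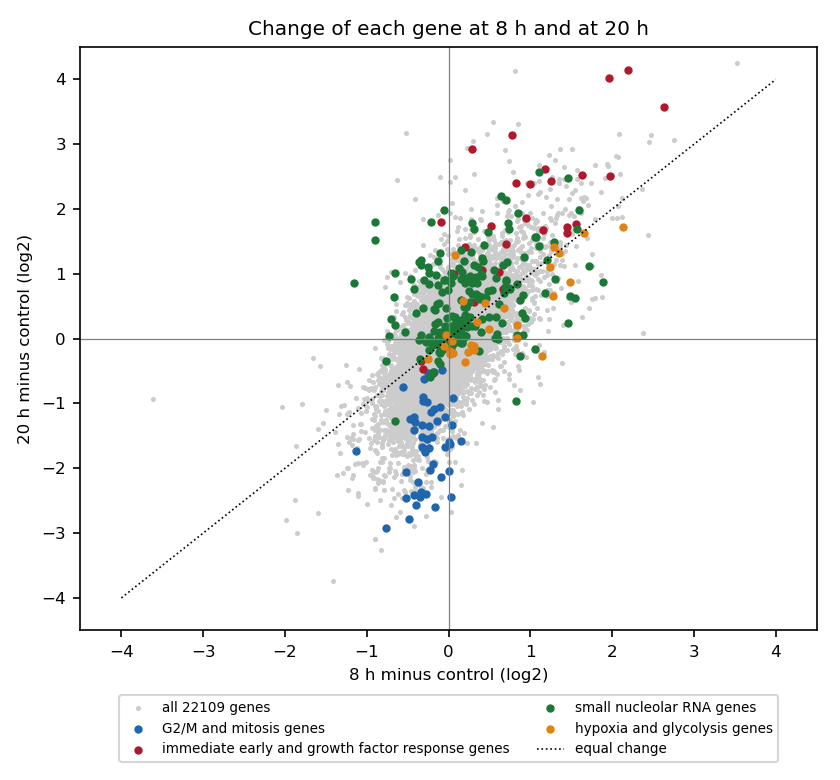
Log2 fold change at 8 h (horizontal axis) and at 20 h (vertical axis) against control for each of 22109 genes (grey), with 4 gene lists coloured. The dotted line marks equal change. The G2/M list has medians of -0.26 at 8 h and -1.55 at 20 h.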

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

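The tests of small RNA and host transcripts below were chosen after the result was seen, and the splits of the arrays and the 20 h against 8 h comparison were planned. The effect against control differed between 20 h and 8 h for several gene groups in limma's test of that difference, although dose changed along with time. The median log2 difference, 20 h minus 8 h, was -1.33 for G2/M and mitosis genes, -0.94 for G1/S and replication genes and -1.09 for recombination and Fanconi genes. It was 0.47 for cholesterol synthesis genes, 0.41 for endoplasmic reticulum chaperones, 0.34 for cytosolic heat shock genes and 0.14 for small nucleolar RNA genes. BIRC5 differed by -0.77. Single outlying values were not tested within groups of 3 arrays.

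Of the 10 ways to split the 6 arrays of a comparison, 1 gave as many called genes in each comparison, the real one. It called 2698 genes at 8 h, 6704 at 20 h and 4991 between 20 h and 8 h, and the highest other split called 0. The other splits mix arrays of both groups, so a real difference raises their spread and leaves few calls. Their 0 calls thus say little about chance. With 10 splits the share cannot fall under 0.05.

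Small nucleolar RNA genes above the median level had a median log2 change of 0.836 at 20 h (95% bootstrap interval 0.698 to 0.909, 131 genes). MicroRNA genes above that level had a median of 0.0618 (-0.0233 to 0.136, 231 genes), so their probe sets showed no such gain. These classes were not matched on level, and dim genes have compressed changes. The comparison thus does not exclude a general gain of small RNA in the 20 h samples. Genes above that level with symbols starting in RNU, pseudogenes such as RNU4-9P included, had 0.407 (-0.191 to 0.866, 24 genes). A gain limited to some classes thus also stays open. A rise of the host transcripts is argued against for 137 small nucleolar RNAs in 83 hosts outside the SNHG and GAS5 genes, whose change exceeded that of the host by a median of 0.367 (0.141 to 0.899) while these hosts had a median of -0.026. For the 11 in SNHG and GAS5 hosts it stays open: those 7 hosts had a median of 0.646, and the difference was -0.388 (-0.494 to -0.0507). A change in processing or stability may remain as a hypothesis for the others and was not tested.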

How the results depend on the processing

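The setting with 8 h replicates 1 and 2 counted as 1 sample was chosen after seeing the data, and the others were planned. Over 19 alternatives, named genes gave 8193 values: 7887 kept their direction and side of the threshold, 276 lost their call, 10 gained one and 20 changed sign, of which 0 had been called. For the gene lists with a call, over 20 alternatives, 1149 of 1239 values kept it, 89 lost it and 1 changed sign. Camera with an estimated correlation gave 39 of the lost calls. The BIRC5 change at 8 h ranged from -0.58 to -0.39, with an adjusted p from 0.00735 to 0.114. With the replicate number as a block, limma called 1133 genes higher and 1071 lower at 8 h, and 2712 and 3619 at 20 h.

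With all probe sets and no collapsing, more probe sets were tested. At 8 h, 2529 were higher and 1724 lower, so that more were higher than lower, against 1310 and 1388 genes, with 878 and 200 at least 2-fold. At 20 h, 5289 were higher and 5640 lower, with 1421 and 1607 at least 2-fold. From 8 h to 20 h, 3198 were higher and 4804 lower, with 627 and 1242 at least 2-fold. The correlation of the 8 h and 20 h changes was then 0.543. When only genes above the median level were tested, camera passed 14 lists at 20 h. With an estimated correlation it passed 7, 9 and 7 lists in the 3 comparisons. Counting 8 h replicates 1 and 2 as 1 sample gave 844 genes lower at 8 h. Leaving out single arrays gave 820 to 1411 genes lower at 8 h and 1314 to 2339 genes higher from 8 h to 20 h, with fewer samples in each fit. Apart from the smaller number of genes or samples, the cause was not tested.

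Signs changed for 7 genes without a call in those comparisons and for the median of the hypoxia list, which was 0.10 at 20 h with all arrays. At 8 h, BIRC6 was at -0.0059 with repeated quantile normalization and -0.0091 with array weights, and BCL2A1 from 8 h to 20 h at 0.021 with array weights. With 8 h replicates 1 and 2 counted as 1, BIRC2 was at 0.0057, BIRC8 at 0.0042 and BCL2 at -0.0033. Leaving out single arrays gave 8 h ranges of -0.051 to 0.020 for BIRC2, -0.035 to 0.068 for BIRC6, -0.044 to 0.40 for BIRC7 (0.22 with all arrays), -0.043 to 0.018 for BIRC8, -0.13 to 0.16 for BCL2 and -0.16 to 0.0041 for SLC35F2. It gave -0.11 to 0.062 for BCL2A1 from 8 h to 20 h, and -0.00067 to 0.18 for the hypoxia list's median at 20 h, where the lowest value came without control replicate 2. The cause was not tested. Genes near the array background have compressed fold changes, which limits what dim genes can show.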

Other observations

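The gene lists in the first paragraphs, and every test on control replicate 3 and on gene length, were chosen after the result was seen. Centromere and kinetochore genes fell together at 20 h, 28 of 29, with a median log2 change of -1.93, and 16 fell at 8 h. Control replicate 3 differed from the other controls by a median of -0.163 for them, and without it 28 fell at 20 h and 16 at 8 h. KNL1, of the outer kinetochore, fell by 2.47 and SPC25, of the NDC80 complex, fell by 2.42. Of 19 condensin and cohesin genes, which fold and hold chromosomes, 18 fell at 20 h and 5 at 8 h, and SMC2 fell by 1.91. Of 11 dual specificity phosphatases, which remove phosphate from MAP kinases, 8 rose at 20 h and 2 fell, and 5 rose and 2 fell at 8 h. DUSP10 rose by 2.19 at 20 h, while DUSP6 fell by 0.46. The phosphatases had a median 0.357 higher in control replicate 3 than in the other controls, and without it 7 rose and 1 fell at 8 h and 8 rose and 2 fell at 20 h. Of 6 GADD45 and SIK genes, 5 rose at 20 h and 4 at 8 h, and GADD45G rose by 2.91 at 20 h. Control replicate 3 was higher for these genes by a median of 0.563, and without it 6 rose at each time.

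Of 17 core clock genes, 8 rose at 8 h and 0 fell, and 11 rose and 1 fell at 20 h. PER1, a clock repressor, rose by 1.35 at 8 h and 2.40 at 20 h. These genes had a median 0.447 higher in control replicate 3 than in the other controls, and without it 11 rose at 8 h and 14 at 20 h. Of 8 genes of 7SK and P-TEFb, which control release of paused RNA polymerase II, 4 rose and 1 fell at 20 h, and 1 rose and 1 fell at 8 h. RN7SK, the 7SK RNA, rose by 2.15 at 20 h (limma adjusted p = 1.21e-06) and differed by -0.41 at 8 h (limma adjusted p = 0.0665). Of 8 small nucleolar RNA host genes, 6 rose and 1 fell at 20 h, and at 8 h 0 rose and 0 fell in limma, or 2 and 0 without control replicate 3. SNHG15 rose by 1.43 and SNHG1 fell by 0.53 at 20 h. By gene type, 41.3% of 213 small nucleolar RNA genes and 34.5% of 16957 protein-coding genes changed at 20 h.

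Control replicate 3 lay apart from the other controls, toward the treated arrays on the first principal component. RNA of 20 h cells mixed into it is argued against by the share that genes down 4-fold would need, 18.1% (12.4 to 22.7, 96 genes), against 7.62% (6.08 to 10.5, 118 genes) for genes up 4-fold. The intervals resampled genes of a single array as if independent. Correlated genes would widen them, so mixing is not excluded. A wrong label is argued against by the mean correlation of control replicate 3 with the other controls, 0.987, above the 0.979 with the nearest treated group. Noise of that array alone is argued against by the correlation of its deviations with the 20 h change across genes, at least 0.390 with no shared arrays. An early response in control replicate 3 may remain as a candidate explanation, but it stays open. The immediate early list had a median deviation of 0.486 there, at percentile 100 of 10000 random lists. Yet that list prompted the explanation, and random lists ignore the correlation among its genes.

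From 8 h to 20 h, short genes tended to be higher and long genes lower, with a Spearman's rho of -0.361 (-0.378 to -0.345) between length and change across 9885 protein-coding genes, which are not independent replicates. Lengths came from a GRCh38.p14 gene table, and rho was 0.11 at 8 h and -0.201 at 20 h against control. The members of the cell cycle and repair lists were not the sole source, since rho without them was -0.365 across 9766 genes. So few genes were left out that rho could hardly have moved. Cell cycle genes outside those lists stayed in, so a wider fall of such genes stays open. Expression level is argued against as the source, with a weakest rho of -0.341 among 3 groups of genes by level. The medians were 0.205 up to 5 kb, 0.016 from 5 to 40 kb, -0.182 from 40 to 80 kb and -0.198 above 80 kb. A loss of transcription along the gene, RNA stability and other features that go with length could remain as candidate explanations: rho was -0.0236 (-0.0548 to 0.00662) among 4214 genes over 40 kb, but that length was chosen after these medians were seen and decides nothing.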
